A study of Homo sapiens with 7 samples.

How the data were processed

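RNA sequencing of the human monocytic line U937 was analysed in 7 libraries of 3 groups. MT_mock held 3 libraries of the parental cells, B412_mock 2 libraries of U937 B412 cells, which express the PLZF/RARA fusion in zinc, and B412_GSK126 2 libraries of B412 cells given GSK126, an inhibitor of the catalytic activity of the histone methyltransferase EZH2. Groups and replicate numbers were taken from the sample titles. Every library had 0.1 mM ZnSO4. Per the labels' protocols, B412 cells were pretreated with zinc for 24 h and then given 2.5 µM GSK126 with zinc for 96 h.

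Per the labels' protocols, total RNA was extracted with a column kit, cDNA was made with a SMART-Seq v3 Ultra Low Input kit, the double-stranded cDNA was sheared by ultrasound, and libraries were made with a NEBNext Ultra DNA kit. SMART-Seq cDNA is primed at poly(A) tails and amplified before sequencing. No molecular identifiers are named, so intervals and floors given here cover counting error only. The protocol does not mark the strand, so reads of overlapping genes on opposite strands were not separated. Per the submitters' processing notes, FastQC, Subread, featureCounts and the build hg19 were used; their versions, roles and the gene annotation are not given in the sources used here. The authors deposited whole-number counts per gene symbol, with no normalization, in 1 table per group and 1 column per replicate. Each table held the same 26364 symbols. No coordinates are given here, since the reference at hand was of a later build; it served only for older gene symbols, GC content and transcript length.

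Total counts lay between 12736244 and 14848130 per library. A floor of 3 counts stood for 0.202 to 0.236 CPM (counts scaled to the library total). Where every library of a group had 0 counts, the fold was computed against 3 counts per library and is a lower bound. Where a group held 1 to 3 counts, the ratio of the summed counts is given with its exact 95% binomial interval.

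Tests were fixed before the data were examined. Counts were filtered with filterByExpr at a minimum count of 10 and a minimum total of 15, which kept 13521 genes and left 12843 untested. They were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust, two-sided) in R 4.3.3, with group means only and all 7 libraries in one fit, since a group of 2 gives little on its own spread. Adjusted p is by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The comparisons were B412_mock against MT_mock, B412_GSK126 against B412_mock and, as a secondary one, B412_GSK126 against MT_mock. The last of these shares libraries with each of the others.

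The libraries fell into 2 sets on the first principal component of log2 CPM (prior count 2), and each set held all 3 groups. Set 1 was MT_mock replicates 1 and 2, B412_mock replicate 1 and B412_GSK126 replicate 1. Set 2 was MT_mock replicate 3, B412_mock replicate 2 and B412_GSK126 replicate 2. No label names a batch. An edgeR fit with the set as an additive term was added after the data were examined, and its values are named throughout as those with the library-set term. Differences within each set were computed from log2 CPM. The common biological coefficient of variation was 58.3% without the term and 21.9% with it, on 4 and 3 residual degrees of freedom. Since the sets were taken from these same counts, part of this fall is built in. The p-values with the term may therefore be too small.

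The procedure was tested on simulated data drawn from these libraries, with 200 of 13521 genes changed. Counts were drawn from the means of each library set, with the dispersions of the fit with the library-set term. Recovery with the term therefore assumes the model under test and may be too high for the real data. The changed genes were picked in a single draw per comparison, only among genes with higher mean counts. The recovery given here therefore does not cover tested genes with low counts. For B412_mock against MT_mock, the fit without covariate recovered 0 of 67 genes changed 2-fold, 0 of 67 changed 4-fold and 0 of 66 changed 8-fold, and the fit with the library-set term recovered 59.7%, 86.6% and 98.5%. For B412_GSK126 against B412_mock, the fit without covariate recovered 0 of each, and the fit with the term 52.2%, 83.6% and 98.5%. Of 13321 unchanged genes the fit with the term called 6 and 15 in these comparisons, the latter beside 35, 56 and 65 recovered genes, a share of false calls above the threshold. In the real data, TMEM158 was 6.83-fold higher with GSK126 and did not pass with the term (edgeR adjusted p = 0.937).

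Gene lists were written before the data were examined, 19 in all. Of 399 list entries 395 were found under the same symbol, 3 under an older one and 1 was not found. The 18 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p is over the lists of a comparison. The named genes follow a rule fixed before the data were examined. ZBTB16, RARA, EZH2 and EZH1 were always named. Where at least 10 genes passed, the rule took the 6 largest rises and 6 largest falls with a mean log2 CPM of at least 2, no overlap between the groups' libraries and a full gene symbol. It also took the 3 called members with the lowest adjusted p of the 6 lists with the largest called share, and the called members of other lists with 3 or fewer. Where fewer than 10 genes passed, the 6 with the lowest p were named as not passing. The rule was applied to both fits. The named gene RNASE2 and some list members (the metallothioneins and HLA genes) have close paralogs, for which reads may be split between copies.

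The alternatives were relative log expression factors, library size only, no filter on low counts, at least 50 counts in at least 2 libraries, DESeq2 1.42.0, limma-voom, only the compared groups in the fit, the replicate number as a block, and leaving out each library in turn. Each except the replicate block was also run with the library-set term. Offsets for GC content and transcript length, and set 1 alone, were added after the data were examined. The values of B412_mock enter 2 comparisons with opposite sign, so unchanged groups sharing these libraries were simulated 25 times to give the correlation and covariance that the sharing alone produces.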

Results

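Gene expression was measured by RNA sequencing in U937 cells, a human monocytic line. MT_mock was the parental line, with 3 libraries. B412_mock, with 2 libraries, was a derivative that expresses PLZF/RARA in zinc. This fusion of the transcriptional repressor PLZF (encoded by ZBTB16) with the retinoic acid receptor alpha (RARA) occurs in a form of acute promyelocytic leukaemia that responds poorly to retinoic acid. B412_GSK126, with 2 libraries, was the same derivative given GSK126 at 2.5 µM for 96 h. All 7 libraries had 0.1 mM ZnSO4. The total counts per library lay between 12736244 and 14848130, and 14727 to 15994 genes had at least 1 count. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

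The largest difference among the libraries did not follow the groups. The first principal component held 65.7% of the variance of log2 CPM and parted the libraries into 2 sets, each with libraries of all 3 groups; the second component, with 15.4%, parted MT_mock from the B412 libraries. Pairs of libraries from the same set correlated at r = 0.937 to 0.985 across genes, and pairs from different sets at 0.818 to 0.889. Of 13521 genes tested, 8320 differed between the sets in an edgeR fit with group and set, 4248 higher and 4072 lower in set 2. The sets were drawn from these same values, so this count and the adjusted p-values between sets are partly built in. EEF2, a translation elongation factor, was higher in set 2 by 2.06 on the log2 scale (adjusted p = 2.84e-08). HSP90AA1, a heat shock chaperone, had a log2 difference of -2.42 (adjusted p = 1.84e-07), and EZH2 itself one of -1.46 (adjusted p = 2.8e-05). Each comparison is therefore given without a set term, as fixed before the data were examined, and with one.

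**Figure D1:**
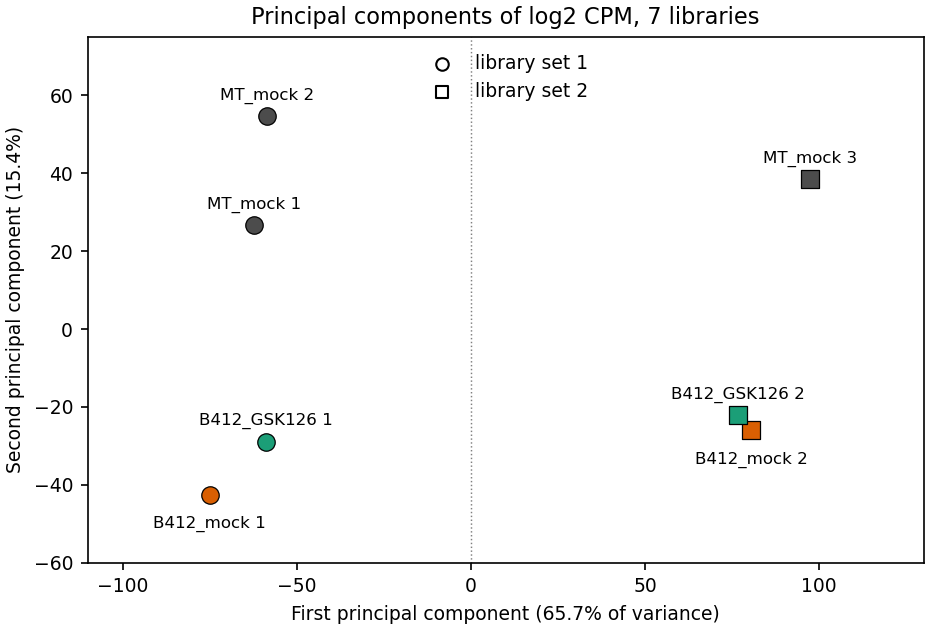
Each point is 1 of the 7 libraries, placed by its first (horizontal, 65.7% of variance) and second (vertical, 15.4%) principal component of log2 CPM, coloured by group, with circles for library set 1 and squares for set 2. The horizontal axis parts the sets, and on the vertical axis the 3 MT_mock libraries lie above all 4 B412 libraries.

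The fusion partners were examined ahead of the other genes. ZBTB16 was read at 22 and 28 counts in the 2 B412_mock libraries and at 7 and 36 in the 2 B412_GSK126 libraries, against 4, 0 and 0 in MT_mock. Its level was 1.88 ± 0.0476 CPM (SD, n = 2) in B412_mock, 1.49 ± 1.34 CPM (SD, n = 2) in B412_GSK126 and 0.0933 ± 0.162 CPM (SD, n = 3) in MT_mock. The log2 difference between B412_mock and MT_mock was 4.19 ± 1.54 (SE), which did not pass the threshold in edgeR (adjusted p = 1). With the library-set term it was 4.08 ± 1.28 (SE, adjusted p = 0.126), and ZBTB16 passed when adjusted over the list alone, a list of 2 genes. With the term ZBTB16 passed in only 2 of 7 other alternatives: DESeq2 (adjusted p = 0.0422) and edgeR without the filter on low counts (adjusted p = 0.0107). It passed in 1 of 7 edgeR fits with a library left out, that without MT_mock replicate 1 (adjusted p = 0.0286). That library is the only one of MT_mock with ZBTB16 counts. The log2 difference of ZBTB16 lay between 3.17 and 7.83 with a library left out. RARA was read at 24.3 ± 8.28 CPM (SD, n = 3) in MT_mock, 26.9 ± 13.3 CPM (SD, n = 2) in B412_mock and 35.1 ± 15.6 CPM (SD, n = 2) in B412_GSK126, a spread that followed the library sets. Its log2 difference between B412_mock and MT_mock was -0.17 within set 1 and 0.10 within set 2, and that between B412_GSK126 and B412_mock 0.47 and 0.35. None of the fits called RARA. These gene-level counts do not separate fusion transcripts from the native genes.

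**Figure D2:**
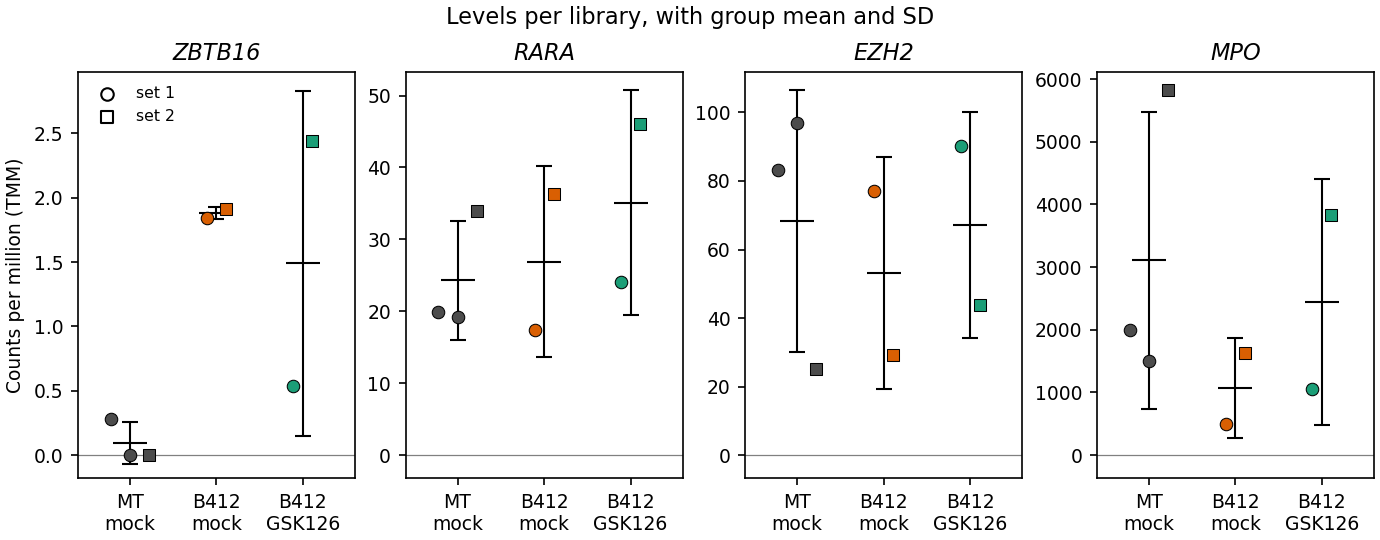
Levels of ZBTB16, RARA, EZH2 and MPO in CPM (linear vertical axes) for each library of the 3 groups, with circles for library set 1, squares for set 2, and the group mean with SD bars. ZBTB16 lies between 1.84 and 1.91 CPM in B412_mock and at most 0.28 CPM in MT_mock; RARA, EZH2 and MPO differ between the sets within every group.

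The comparison of B412_mock with MT_mock asks how cells of the PLZF/RARA line differ from the parental line, both in zinc. The largest differences were genes read in one line and nearly absent from the other. GPC4, a cell-surface heparan sulfate proteoglycan, had 261 counts in B412_mock and 0 in MT_mock, at least 43.5-fold higher against a floor of 3 counts per library. SLC27A2, a very long-chain acyl-CoA synthetase, and PTPRF, a receptor tyrosine phosphatase, had 1111 and 1105 counts in MT_mock and 0 in B412_mock, at least 116-fold and 115-fold lower. MPO, the myeloperoxidase of neutrophil granules, was 3.54-fold lower in B412_mock. These genes passed the threshold of the edgeR fit with the library-set term.

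With the library-set term, edgeR called 318 of 13521 genes, 115 higher and 203 lower in B412_mock, and all 318 had the same sign within both sets, which their selection by this fit nearly fixes. Without the term, the test fixed beforehand called 0 genes, with 343 at an unadjusted p under 0.05. By chance 676 would be expected if libraries differed only at random, which the split into sets makes untrue. Without the term DESeq2 called 95 and limma-voom 0. The 318 calls depended on the B412_mock libraries and on each MT_mock library: edgeR with the term called 33 without B412_mock replicate 1, 57 without B412_mock replicate 2, 587, 161 and 205 without MT_mock replicates 1, 2 and 3, and edgeR within set 1 alone, where B412_mock is 1 library and the only spread is that between 2 MT_mock libraries, called 147. The B412 line and the fusion cannot be separated, since no B412 library without zinc was analysed here.

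AUTS2 and HDAC9, the latter a class IIa histone deacetylase, had 227 and 209 counts in B412_mock against 1 each in MT_mock, ratios of 357 (95% counting interval 63.5 to 14200) and 329 (58.4 to 13100). UROC1, an enzyme of histidine breakdown, rose 47.5-fold (log2 change 5.57 ± 0.381 SE, edgeR adjusted p = 8.73e-05). CACNA2D2, a calcium channel subunit, and CPZ, a carboxypeptidase, rose 30.6-fold and 27.6-fold, both with an adjusted p of 0.000399. Among the falls, PIR, an iron-binding nuclear protein, had 432 counts in MT_mock and 0 in B412_mock, at least 45.4-fold lower. ACTL8, GALNT14, a glycosyltransferase of mucin-type O-glycosylation, and TMEM54 had 1502, 1189 and 550 counts in MT_mock against 2, 3 and 1 in B412_mock. Their ratios were 477 (95% counting interval 132 to 3940), 252 (85.9 to 1220) and 349 (62.4 to 13800). These 12 genes stayed past the threshold of the fit with the term whichever library was left out; lack of overlap between the groups was part of the rule that chose them. Over all tested genes 11.8% had no overlap between the groups, where chance gives 20% with 2 against 3 libraries that differ only at random. The 2 sets cross the groups and break that assumption, so 11.8% cannot be read against 20%. In the fit without the term, PTPRF, AUTS2, UROC1, HDAC9, CACNA2D2 and ACTL8 were the 6 genes with the lowest p and did not pass, with adjusted p between 0.248 and 0.282.

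**Figure D3:**
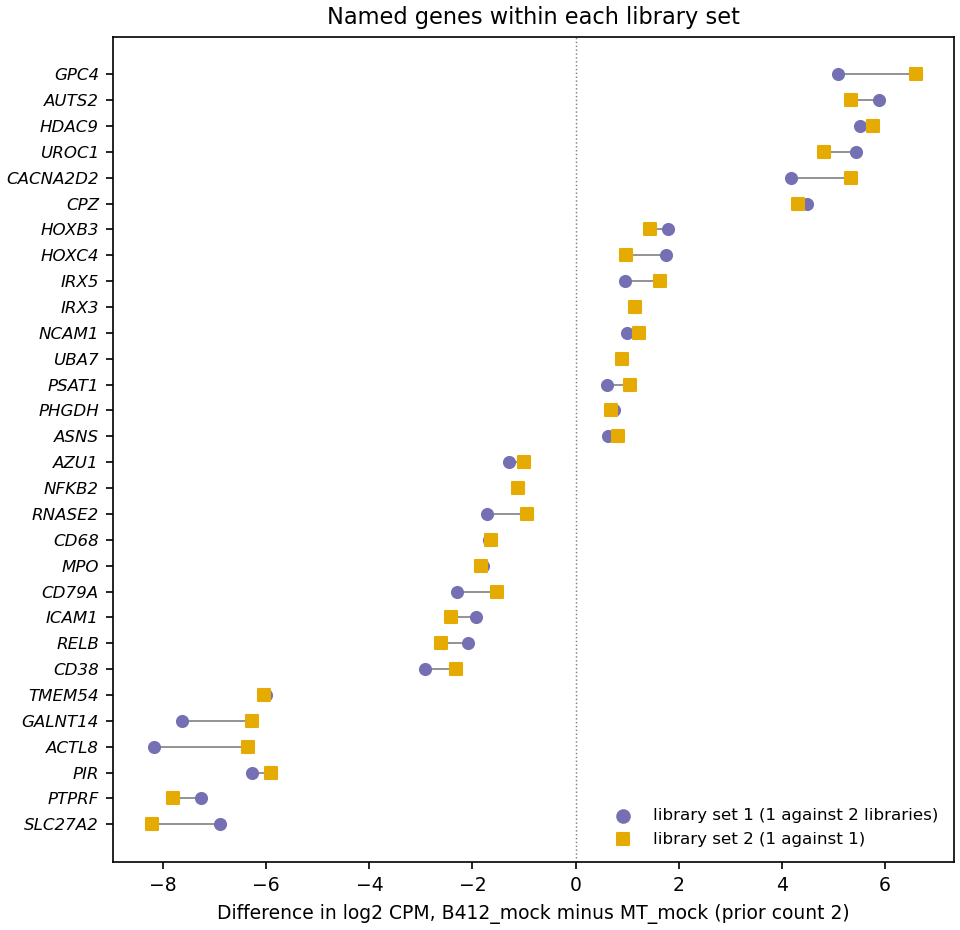
Difference in log2 CPM between B412_mock and MT_mock (horizontal axis, prior count 2) within library set 1 (circles) and within set 2 (squares) for the named genes that passed the threshold with the library-set term, 1 gene per row. Every gene lies on the same side of 0 in both sets, for example MPO at -1.79 and -1.84.

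Granulocyte granule and neutrophil genes were lower in B412_mock as a list. Of 13 tested members 12 had a negative log2 change, with a median of -1.28 with the library-set term. That fit called 4, all lower, and 8, all lower, when adjusted over the list alone; the fit without the term called 0 and 0. MPO fell by 1.82 ± 0.143 on the log2 scale (SE, edgeR adjusted p = 0.000212), from 3110 ± 2370 CPM (SD, n = 3) to 1070 ± 796 CPM (SD, n = 2), and its spread within a group followed the sets. RNASE2, a granule ribonuclease, and AZU1, an antimicrobial granule protein, fell 2.66-fold (adjusted p = 0.00763) and 2.24-fold (adjusted p = 0.016). RNASE2 lost its call without B412_mock replicate 1 (adjusted p = 0.401). AZU1 lost its call without either B412_mock library or MT_mock replicate 3. The camera adjusted p was 8.8e-09 without the term and 5.62e-11 with it, and with an estimated correlation adjusted p = 0.189 and adjusted p = 0.0947.

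Inflammatory cytokine and NF-kappaB target genes were also lower as a list, with 13 of 16 tested members negative and a median log2 change of -0.92 with the term. RELB, an NF-kappaB subunit, fell 5.21-fold (edgeR adjusted p = 0.0049) and NFKB2, the precursor of its partner p52, fell 2.27-fold (adjusted p = 0.0433). NFKB2 was called in 5 of 8 other alternatives and in 3 of 7 fits with a library left out, the only named call lost in the former. In the list 7 members passed when adjusted over the list alone, 6 of them lower. Camera gave adjusted p = 7.92e-06 without the term and 0.000254 with it; with an estimated correlation adjusted p = 0.433 and adjusted p = 0.591. Zinc-responsive metallothioneins and the zinc exporter were lower in 10 of 10 members, with a median of -0.85 with the term, but no member passed in either fit, over all genes or adjusted over the list alone. Camera gave adjusted p = 3.76e-06 without and 0.00109 with the term, and with an estimated correlation adjusted p = 0.411 and adjusted p = 0.591. Metallothionein genes took 0.643% of all counts in B412_mock replicate 2 and 1.46% to 2.84% in the other 6 libraries. The zinc dose was the same in all, but a pretreatment time is given only for B412 cells, so equal zinc exposure of the lines is not known.

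Genes of the integrated stress response and amino acid synthesis were higher in B412_mock, with 15 of 20 members positive and a median of 0.36 with the term. PHGDH and PSAT1, enzymes of serine synthesis, rose 1.66-fold (edgeR adjusted p = 0.0139) and 1.73-fold (adjusted p = 0.0252), and ASNS, asparagine synthetase, rose 1.63-fold (adjusted p = 0.047). These were the 3 calls, and 7 members, all higher, passed when adjusted over the list alone. Camera gave adjusted p = 0.000148 without and 0.000226 with the term, and with an estimated correlation adjusted p = 0.295 and adjusted p = 0.18. Cholesterol biosynthesis genes had 15 of 20 members positive and a median of 0.44 with the term. None was called over all genes and 2 were, both higher, when adjusted over the list alone. Camera gave adjusted p = 2.8e-06 without and 0.000226 with the term, and with an estimated correlation adjusted p = 0.433 and adjusted p = 0.591. These 5 lists were those past the camera threshold in both fits; without B412_mock replicate 2 the fit without the term gave 3 lists.

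In 5 other lists genes were called while camera did not pass for the list. Of 11 retinoic acid target genes, ICAM1, an adhesion molecule, and CD38, a surface enzyme induced by retinoic acid in myeloid cells, fell 4.38-fold (edgeR with the term, adjusted p = 0.00532) and 6.98-fold (adjusted p = 0.0118), while UBA7, the activating enzyme for ISG15, rose 1.89-fold (adjusted p = 0.0239). Adjusted over the list alone, 5 members passed, 2 higher and 3 lower. Of 13 developmental regulators, IRX3 and IRX5, homeobox genes that lie next to each other, rose 2.26-fold (adjusted p = 0.00147) and 2.47-fold (adjusted p = 0.0235). Of 18 HOX genes, HOXB3 rose 3.25-fold (adjusted p = 0.0149) and HOXC4 rose 2.71-fold (adjusted p = 0.0296). These 4 were also the calls adjusted over the list alone. Of 13 monocyte and macrophage genes, CD68, a lysosomal glycoprotein, fell 3.1-fold (adjusted p = 0.00662), and 2 members, both lower, passed adjusted over the list alone. Of 9 markers of T, B and NK cells, NCAM1 rose 2.12-fold (adjusted p = 0.00605) and CD79A, a B-cell receptor component, fell 4.33-fold (adjusted p = 0.0197), and 5 members passed adjusted over the list alone, 3 higher and 2 lower (3 without the term, 1 higher and 2 lower). Of the 18 called members named for these lists, MPO kept its call whichever library was left out and 17 lost it without at least 1 library, mostly a B412_mock library, and none changed sign.

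**Figure D4:**
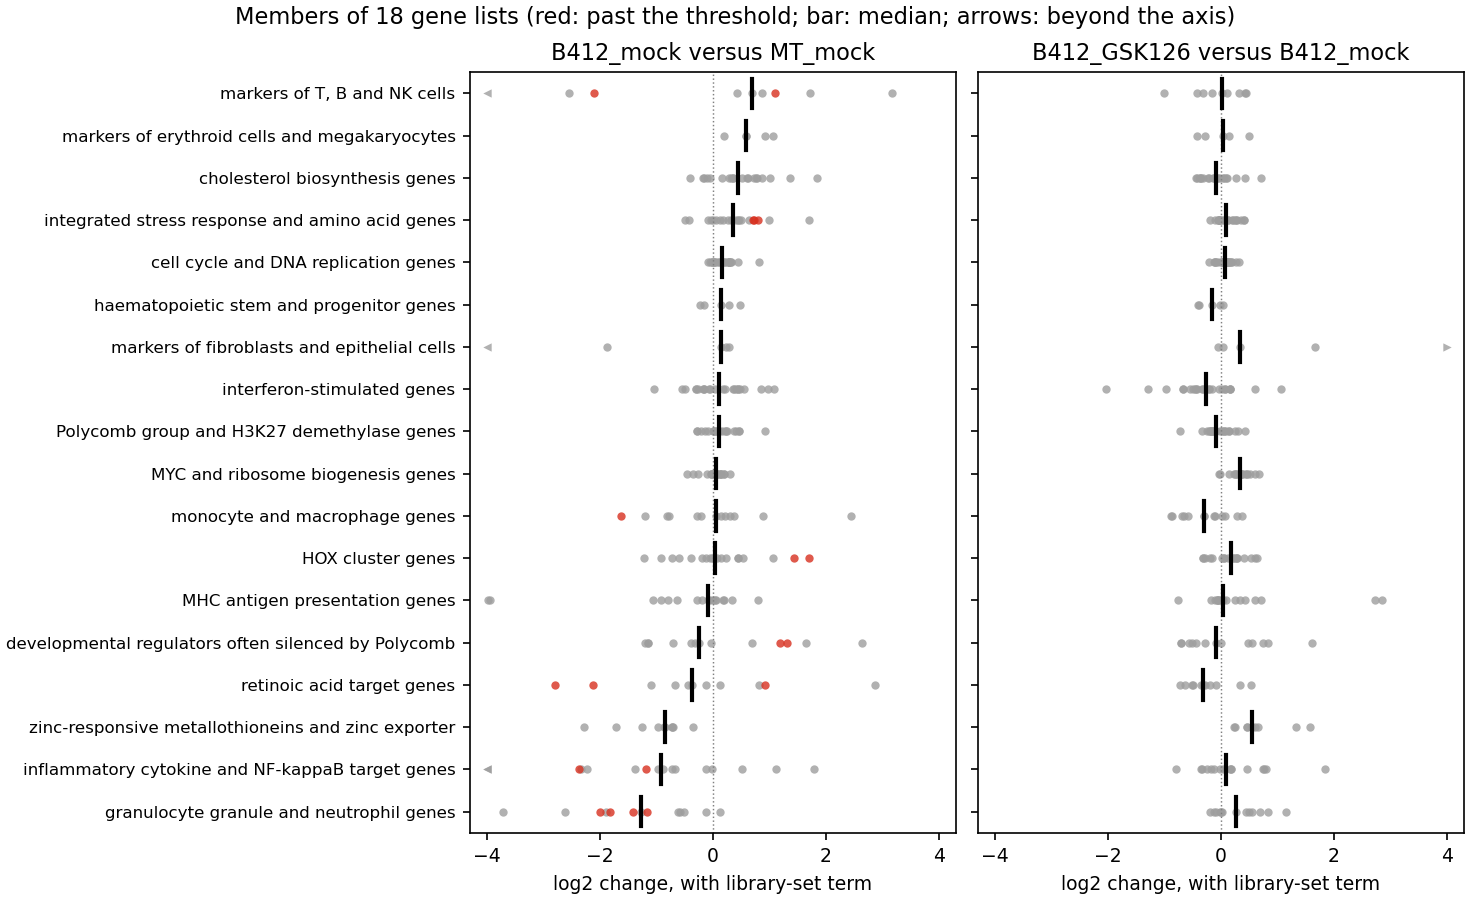
Log2 changes with the library-set term (horizontal axis) of the tested members of 18 gene lists (rows) in B412_mock against MT_mock (left) and B412_GSK126 against B412_mock (right); each point is a gene, red where it passed the threshold, black bars are medians, and arrowheads mark genes beyond the axis. On the left the granulocyte list has the lowest median, -1.28; on the right no point is red and the metallothionein list has the highest median, 0.54.

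No member passed over all genes in the lists of MHC antigen presentation (17 tested), MYC and ribosome biogenesis (20), Polycomb group and H3K27 demethylase (22), cell cycle (24), interferon-stimulated (24), haematopoietic stem and progenitor (5), erythroid and megakaryocyte (5) and fibroblast and epithelial genes (5), with or without the term. Adjusted over the list alone, only 1 member of the fibroblast and epithelial list passed, which was lower, in the fit with the term. Camera gave no adjusted p under 0.0517 among them. The median was positive and the camera direction down for the fibroblast and epithelial and the monocyte lists, and the reverse held for developmental regulators, in the fit with the term. EZH2, the target of GSK126, was at 53.1 ± 33.8 CPM (SD, n = 2) in B412_mock and 68.3 ± 38.1 CPM (SD, n = 3) in MT_mock, and EZH1 at 30.3 ± 17.1 CPM (SD, n = 2) and 30.9 ± 9.84 CPM (SD, n = 3). Their log2 differences with the term were -0.08 ± 0.206 and 0.07 ± 0.236 (SE), of opposite sign in the 2 sets for each, and neither passed.

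The comparison of B412_GSK126 with B412_mock asks what inhibition of EZH2 catalysis did to expression in the PLZF/RARA line. No gene passed the threshold in either edgeR fit. MPO came nearest: it was at 503 and 1630 CPM in the 2 B412_mock libraries and at 1050 and 3830 CPM in the 2 B412_GSK126 libraries, higher with GSK126 by 1.07 on the log2 scale within set 1 and by 1.23 within set 2. The log2 change was 1.15 ± 0.147 (SE) with the library-set term (adjusted p = 0.0754). EZH2 was at 67.1 ± 32.9 CPM (SD, n = 2) with GSK126 and EZH1 at 28.6 ± 19.4 CPM (SD, n = 2), with log2 changes of 0.42 ± 0.222 and -0.14 ± 0.258 (SE) with the term, neither past the threshold. ZBTB16 had a log2 change of -0.45 ± 1.14 (SE) and RARA one of 0.40 ± 0.22 (SE), neither past it.

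Without the term edgeR had 32 genes at an unadjusted p under 0.05, 31 of them higher with GSK126. The 676 expected by chance again assumes libraries without a split into sets. Without the term DESeq2 and limma-voom called 0. With the term there were 464, 298 higher and 166 lower. DESeq2 with the term called 4 genes, all higher with GSK126: MPO, GALNT14, IGFBP2 and TMEM158. Limma-voom with the term called 1, MPO. EdgeR with the term called 14 when only the B412 libraries were fitted, all higher, and 34 without the filter on low counts, 33 higher. All of the 14 but PODXL were also among the 34, with MPO, IGFBP2, TMEM158, DGAT2 and KAZN in both, but both fits use the same B412 libraries. The fit of the B412 libraries alone leaves 1 residual degree of freedom. Without the filter MPO had a log2 change of 1.16 (edgeR adjusted p = 2.73e-11), against 1.15 (adjusted p = 0.0754) with it. The p-value fell there with almost no change in effect, so the genes in both are not independent support. The log2 changes of set 1 and set 2, which share no library, correlated at r = 0.247 across 10737 genes, with 57.6% of genes of the same sign. The same correlation was 0.617 for B412_mock against MT_mock; genes are not independent replicates.

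The 6 genes with the lowest p with the term were higher with GSK126 and did not pass. After MPO came IGFBP2, an insulin-like growth factor binding protein, at 383 ± 24 CPM (SD, n = 2) against 209 ± 19.5 CPM (SD, n = 2) in B412_mock, and TMEM158 at 9.03 ± 2.65 against 1.31 ± 0.662 CPM, each with an edgeR adjusted p of 0.937. GALNT14 had 71 counts against 3, a ratio of 22.7 (95% counting interval 7.45 to 113, adjusted p = 0.937). DGAT2, an enzyme of triglyceride synthesis, and KAZN had log2 changes of 1.18 ± 0.248 and 1.31 ± 0.28 (SE), both with an adjusted p of 1. Without the term the 6 lowest p, each with an adjusted p of 1, belonged to TMEM158, GALNT14, PTPRF, FIBCD1, ECHDC2 and ACTL8. PTPRF, FIBCD1 and ECHDC2 had 20, 26 and 14 counts with GSK126 and 0 in B412_mock, at least 3.22-fold, 4.13-fold and 2.28-fold higher, and ACTL8 had 23 against 2, a ratio of 11 (95% counting interval 2.72 to 96.5). PTPRF, GALNT14 and ACTL8 were also among the genes with the largest falls in B412_mock against MT_mock, and with GSK126 PTPRF and GALNT14 stood at 0.733 and 2.47 CPM against 26.3 and 28.3 CPM in MT_mock.

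As lists, metallothioneins and the zinc exporter were higher with GSK126 in 10 of 10 members (median log2 change 0.54 with the term), and MYC and ribosome biogenesis genes in 18 of 20 (median 0.34). Interferon-stimulated genes were lower in 16 of 24 members (median -0.26) and monocyte and macrophage genes in 9 of 13 (median -0.30). Camera adjusted p was 7.42e-05, 0.00698, 0.00698 and 0.0166 for these 4 lists without the term and 0.00498, 1.07e-05, 0.00568 and 0.0081 with it. Granulocyte genes, with 9 of 13 members higher (median 0.27), passed only with the term (adjusted p = 0.0225; 0.167 without). With an estimated correlation none passed: adjusted p = 0.596 without the term and adjusted p = 0.561 with it for each of these 5. No member passed over all genes, and adjusted over the list alone only 1 granulocyte gene did, higher, with the term. The metallothionein difference was in set 2 alone, with medians of -0.04 in set 1 and 1.15 in set 2, and 5 of 10 members positive in set 1; it moved with the low metallothionein share of B412_mock replicate 2. Of MYC and ribosome biogenesis genes 13 of 20 were positive in set 1 and 19 in set 2. Without B412_mock replicate 2, the fit without the term gave 0 lists; it gave 2 without B412_GSK126 replicate 1 and 1 without B412_GSK126 replicate 2. With the term, leaving out these same 3 libraries gave 2, 8 and 3 lists.

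The remaining 13 lists did not pass camera with GSK126 in either fit and had no called member. Retinoic acid target genes had 9 of 11 members negative (median -0.31, camera adjusted p = 0.0512 with the term). Developmental regulators often silenced by Polycomb had 6 of 13 positive, HOX genes 13 of 18, Polycomb group and H3K27 demethylase genes 9 of 22, MHC antigen presentation genes 10 of 17 and cell cycle genes 18 of 24. Inflammatory genes had 9 of 16 positive, stress response and amino acid genes 12 of 20, cholesterol genes 7 of 20 and stem and progenitor genes 1 of 5. Markers of T, B and NK cells had 5 of 9 positive, erythroid and megakaryocyte markers 3 of 5 and fibroblast and epithelial markers 4 of 5. The last list had a median of 0.34, or 0.04 with a gene at 0 counts in 1 group set to its bound. The number of tested members sets how well a list can be read: 26 of the 39 developmental regulators listed had too few counts to be tested.

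B412_GSK126 was also compared with MT_mock, the end point of both differences. EdgeR with the library-set term called 257 genes, 113 higher and 144 lower, of which 175 were called in the same direction in B412_mock against MT_mock and 0 in the opposite direction; both comparisons use the MT_mock libraries, so shared calls in one direction are partly built in. Without the term edgeR called 0, with 268 at an unadjusted p under 0.05, DESeq2 65 and limma-voom 0. SLC27A2, GPC4 and others kept the level of B412_mock with GSK126: SLC27A2 had 0 counts and GPC4 9.44 ± 6.38 CPM (SD, n = 2) against 9.35 ± 6.46 CPM (SD, n = 2) in B412_mock. The 257 calls became 693, 97 and 132 without MT_mock replicates 1, 2 and 3, 125 and 128 without B412_mock replicates 1 and 2, and 144 and 72 without B412_GSK126 replicates 1 and 2.

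Whether genes that differ between the lines moved back with GSK126 was asked over the comparisons that share B412_mock. No gene was called in both, in either edgeR fit, since none was called with GSK126; DESeq2 with the term shared 3 genes and edgeR with the term and no filter 27. Across genes the log2 changes correlated at r = -0.343 without the term and -0.376 with it. Simulated unchanged groups that share the B412_mock libraries gave -0.48 (-0.51 to -0.449 over 25 draws) and -0.54 (-0.561 to -0.516). Unchanged groups hold no line difference: with the term they gave 0.96 lower genes on average, where 203 were called. A simulation with the term that kept the line difference and left GSK126 without effect gave -0.272 (-0.305 to -0.226). The observed -0.376 was more negative than this range and less negative than that of unchanged groups. The covariance was -0.0599 against a simulated -0.058 without the term, and -0.0682 against -0.0516 with it, or -0.0546 (-0.0624 to -0.0464) where the line difference was kept. Of the 203 genes lower in B412_mock, 79.3% had a positive log2 change with GSK126, with a median of 0.33, where the simulation that kept the line difference gave 66.1% (61.6% to 71.1%) and 0.14. Of the 115 genes higher in B412_mock, 61.7% had a negative change, where the same simulation gave 69.6% (63.1% to 77.4%).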

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

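The genes called without covariate were 0 in each comparison. For B412_mock against MT_mock they became 318 with the library-set term, 147 in set 1 alone (1 B412_mock library), 95 with DESeq2 and 5 with no filter on low counts (ACTL8 and PTPRF lower, UROC1, HDAC9 and AUTS2 higher). For B412_GSK126 against MT_mock they became 257 with the library-set term, 87 in set 1 alone and 65 with DESeq2. Every other alternative and every left-out library gave 0 genes in all 3 comparisons. The cause of the split into sets was not tested by these alternatives.

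After removal of group means, libraries of B412_mock and B412_GSK126 with the same replicate number correlated at r = 0.847. With 2 libraries in each B412 group the deviations mirror each other, so 0.847 is a single value for both numbers. MT_mock replicate 1 correlated with B412 replicate 1 at 0.664 and 0.623, but MT_mock replicate 2 with B412 replicate 2 at -0.634 and -0.635. The latter libraries lie in different library sets, which these values follow. They cannot tell whether equal numbers mark paired cultures. A replicate block left 0 genes called in each comparison, with 890 at an unadjusted p under 0.05 for B412_mock against MT_mock and 60 with GSK126, against 343 and 32 without it.

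With the library-set term, B412_mock against MT_mock went from 318 genes to 881 with no filter and 684 with DESeq2, and to between 33 (without B412_mock replicate 1) and 587 (without MT_mock replicate 1). B412_GSK126 against B412_mock went from 0 to 34 with no filter, 14 with the 2 groups alone, 4 with DESeq2 and 1 with limma-voom, and to between 0 and 3 with a library left out: MPO without MT_mock replicate 1, and MPO, GALNT14 and CLGN without B412_GSK126 replicate 1. B412_GSK126 against MT_mock went from 257 to 892 with no filter, 604 with DESeq2 and 102 with the 2 groups alone, and to between 72 and 693 with a library left out. The overlap between the comparisons that share B412_mock went from 0 to 27 genes with no filter and 3 with DESeq2.

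The lists past camera without covariate were 5 for B412_mock against MT_mock and 4 with GSK126; with an estimated correlation and with fry they were 0 and 0. Leaving out a library gave 3 to 6 and 0 to 5. With the library-set term they were 5 and 5, became 0 and 0 with an estimated correlation, 2 and 0 with fry, and 3 with GSK126 where no filter was used. Leaving out a library gave 4 to 6 and 2 to 8.

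Genes that were never called changed sign. For B412_mock against MT_mock, RARA was at 0.143 without covariate, -0.05 with the library-set term and -0.17 in set 1 alone. Without covariate and with a library left out it lay between -0.50 and 0.58. EZH1 was at -0.0271 without covariate, 0.0713 with the term, 0.00899 with GC and length offsets and 0.25 in set 1 alone. EZH2 was at -0.364 without covariate. Without covariate and with a library left out, EZH1 lay between -0.75 and 0.45 and EZH2 between -1.22 and 0.17. With the term and a library left out, RARA lay between -0.149 and 0.0525, EZH1 between -0.0641 and 0.32 and EZH2 between -0.309 and 0.0416.

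For B412_GSK126 against B412_mock, with a library left out, ZBTB16 lay between -1.79 and 0.39, RARA between -0.17 and 1.03, EZH2 between -0.26 and 1.19 and EZH1 between -1.02 and 0.64. With the term ZBTB16 lay between -2.21 and 0.69 and EZH1 between -0.44 and 0.12. Each group of B412 cells has 2 libraries, so leaving 1 out leaves a single library in that group.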

Other observations

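The test on GC content and length was set before its result was seen; the other tests here were chosen after.

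Genes read at 1 or more counts were more often detected only with GSK126 than only without it. FIBCD1 had 13 and 13 counts with GSK126, and COL27A1, a fibrillar collagen, 15 and 6, and both had 0 in B412_mock; these genes were named after their counts were seen.

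With at least 1 count in both libraries of one B412 group and 0 in both of the other, 177 genes were read only with GSK126 and 86 only without it, and 88 of the 177 had 3 or fewer counts over the 3 MT_mock libraries. After all 4 libraries were drawn down to 12736244 counts they were 177 and 91. The share seen only with GSK126 had a lower 95% bound of 60%, which argues against depth. This bound is over genes and holds no spread between libraries. With at least 5 counts the numbers were 9 and 2, or 81.8% (48.2% to 97.7%), an interval that covers an even split. A lower number of distinct molecules in the B412_mock libraries stays open, as does the loss of H3K27 methylation at silent genes, for which no chromatin data were used.

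Genes low in B412_mock were often higher with GSK126. To avoid shared libraries, genes at least 2 log2 units lower in B412_mock were chosen in one set and their change with GSK126 was read in the other. Of 168 chosen in set 1, 123 rose, 39 fell and 6 stayed level in set 2 (75.9% of those that moved, lower 95% bound 68.6%), which argues against chance values of the shared libraries there, and of 94 chosen in set 2, 61 rose, 26 fell and 7 stayed level in set 1 (70.1%, lower bound 59.4%); each is 1 library against 1, so the bounds are over genes and hold no replicate spread. Carry-over of MT_mock material is argued against by SLC27A2, which, with 0 counts in all B412 libraries, limits it to 0.502% of the MT_mock level, while the median gain in set 2 was 10.3% (7.27% to 14.4%) and in set 1 4.61% (1.77% to 6.91%). Of genes of the same level with no line difference that moved, 48.2% rose in set 2 but 62.2% in set 1. A partial return towards the parental level may thus hold in set 2 for some genes lower in B412_mock, from 1 library against 1. In set 1 a return cannot be told apart from fewer molecules captured in B412_mock, so the matched genes do not decide the question over both sets. Of 8 genes with 0 counts in B412_mock and at least 200 in MT_mock, 5 had 0 counts with GSK126 and 3 had some. Genes at least 2 log2 units higher in B412_mock showed no clear return. Of 54 chosen in set 1, 37% rose in set 2 (95% interval 24.3% to 51.3%). Of 68 chosen in set 2, 48.5% rose in set 1 (36.2% to 61%). Both intervals cover an even split.

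The 2 library sets were the largest structure in these data and crossed all 3 groups, so no biological explanation from the design was tested. They held 65.1% of the variance of genes with a known GC content and length (96.8% of those tested), and 62.5% after each library's trend with GC content and length was removed, which argues against such a bias as the whole cause. RNAs without a poly(A) tail were lower in set 2: the median log2 difference was -2.44 (95% interval -3.03 to -1.37) for 34 replication-dependent histone genes and -2.19 (-2.97 to -1.59) for 69 small nucleolar RNA genes. Different capture of such RNAs is a candidate explanation for part of the split, not for all of the 8320 genes that differed. Among these were EEF2, HSP90AA1 and EGR1, the last with a log2 difference of -7.74. No cause other than such capture and GC content and length was tested.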
